A study of Mus musculus with 2 samples.

How the data were processed

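The data are H3K4me3 chromatin immunoprecipitation and sequencing of mouse facial prominence at embryonic day 15.5, in 2 biological replicates that the labels describe as pools of embryos of both sexes (78 and 62 embryos). The sources used here are 4 peak lists on build mm10: 1 per replicate, 1 called on the pooled replicates and 1 of replicated peaks. The pooled and replicated lists are values of the whole series with no replicate of their own, so they carry no SD or n. The aligner, the peak caller, their settings and the control used are not given in the sources used here. The signal value of each deposited peak, called enrichment here, is the authors' own, and what it is relative to is not stated. The deposited lists also give a −log10 p-value and a −log10 q-value per peak, made by the authors' caller. The lists hold peaks down to a p of 0.01, so they include many weak peaks. The rule that made the replicated list is not given in the sources used here. The lists hold no read counts, so depth per replicate is unknown, and no interval that needs it is given. A deeper library can give more and wider peaks, so numbers and widths of the replicates are compared with that limit.

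The annotation was GENCODE release M21 and the sequence the matching reference of the same build. All peaks on chromosomes 1 to 19, X and Y end inside the reference lengths. Regions on unplaced scaffolds, 10 in the replicated list, stayed in counts of peaks and were left out where an annotation was needed. Of the pooled list's rows, the replicated list's 25183 were found with identical coordinates and values. Peaks were called shared where an overlap covered at least 50% of either peak. A gene had a promoter peak where a region of the replicated list overlapped by at least 1 bp the window of 1 kb on each side of any start of its protein-coding transcripts (54355 starts of 21829 genes, after 27 repeated symbols were joined). Domains are replicated regions merged within 1 kb, and a gene's width is that of the widest domain at its promoter. A region that covers the starts of several genes counts for each of them. CpG content was taken over the 1000 bp centred on the most upstream start, with rich at an observed/expected ratio of at least 0.6 and GC of at least 55%, and poor at 0.4 or less. Regions more than 5 kb from every annotated start, of any kind of transcript, were taken as away from starts.

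There were 28 gene lists (facial mesenchyme and signalling, bone, cartilage, muscle, epithelium, nerve, vessels, blood, other organs, housekeeping and gene families), and 1 symbol of them, Ahsp, was not in the annotation. The lists, the tests, the rule for named genes and the main alternatives were fixed before the data were examined. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at 0.05. The median width of each list with at least 5 marked members was compared with 10000 random lists of the same size drawn from all genes with a promoter domain (two-sided permutation p, adjusted over the lists). Genes are the units of these tests and are not independent replicates, so a p describes the list in these samples. With 1 group there was no test between conditions, and no pairing of replicate numbers across groups. Genes were named by rule: per list, the 2 to 4 marked members with the highest enrichment percentile averaged over the replicates and up to 4 unmarked ones in alphabetical order, then the genes of the 20 widest domains, of the 10 strongest promoter regions, of the 5 strongest regions away from starts and of the 5 strongest regions per replicate with no overlap in the other. Genes named beyond this rule were chosen after their values were seen. They are Kmt2d, Col1a1 and the receptor genes with a peak, the neighbours of shared regions, Cd68, Spi1, Tie1 and Hoxa11. The lowest marked members of the muscle, endothelial and later Hox lists were also chosen in this way.

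The list test was tested on simulated peaks for the real 21829 genes: in 100 runs it found 99.0% of lists in which 95% of members were marked against 60% of all genes, and 0.5% of unchanged lists. The width test found 17 of 25 lists widened 1.6-fold and none of 73 unchanged lists. Simulated calls and widths were drawn gene by gene, without regard to CpG content or shared regions. The shares of unchanged lists found thus need not hold for real lists, which can differ in CpG content. Alternatives were another overlap rule, stricter q-value limits, other promoter windows, merging distances and distances from starts, the pooled list, each replicate's own list in place of the replicated list, and a single start per gene. Further alternatives were added after the data were seen: random lists matched on CpG content, leaving out genes whose regions all cover another gene's window, and starts of a second annotation (NCBI RefSeq) of the same build. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1 indexed the sequence.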

Results

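H3K4me3, trimethylation of lysine 4 of histone H3, marks the start sites of active genes and of many silent genes with CpG-rich promoters. It was measured by chromatin immunoprecipitation and sequencing in the facial prominences of mouse embryos of strain B6NCrl at embryonic day 15.5. There was 1 group of 2 biological replicates, each a pool of embryos of both sexes (78 embryos in replicate 1 and 62 in replicate 2). No second tissue, stage or condition was in the series as analysed here, so nothing was contrasted between groups. The comparisons are those between the replicates, between kinds of genes and between kinds of places in the genome. The peak lists give no read counts, so the depth behind each peak is unknown.

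The mark covered nearly the same parts of the genome in both replicates. Replicate 1 had 30568 peaks and replicate 2 had 29803 (mean 30185.5 ± 541, SD, n = 2). They covered 38.5 and 38.7 Mb, and 34.8 Mb were covered in both, which is 90.5% of the covered bases of replicate 1 and 90.04% of those of replicate 2. Of the peaks of replicate 1, 81.1% had a counterpart in replicate 2 (an overlap of at least 50% of either peak), and 82.3% of the peaks of replicate 2 had one in replicate 1. Sharing followed the rank of the peak by p-value. All of the top 10000 peaks of each replicate were shared, 98.7% and 98.9% of the next 10000, and 46.6% and 47.4% of the rest. Unshared peaks had a median enrichment of 2.86 in replicate 1 and 2.95 in replicate 2, against 19.003 and 21.7 for shared peaks, and a median width of 239 and 244 bp against 1307.5 and 1342 bp. Enrichment is the value the authors' peak caller gave each peak, and what it is relative to is not stated, so values are printed as given and the replicates are compared by rank.

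The authors also deposited a list called on pooled replicates, with 32132 peaks, and a replicated list with 25183 peaks, which was an exact subset of the pooled list (78.4% of it). Of the replicated peaks, 93.6% had a counterpart in both replicates, 1517 in 1 of them and 97 in neither. None of the 6949 pooled peaks left out had a counterpart in both replicates. Their median enrichment was 2.53, against 21.4 for the replicated peaks. Every pooled peak with a counterpart in both replicates was thus in the replicated list. The rule that made that list is not given. The shares with a counterpart may follow from it and are no separate measure of agreement. Across the 23569 replicated regions with a peak in both replicates, Spearman's rho of the enrichment was 0.94. Regions are not independent replicates, so no p-value was computed.

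**Figure D1:**
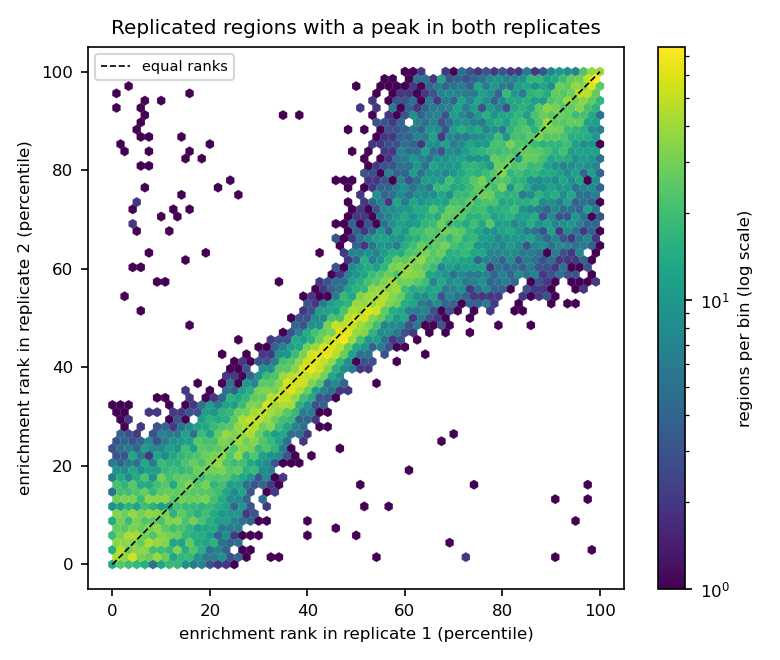
Rank of the strongest peak's enrichment at each of the 23569 replicated regions found in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, each as a percentile among these regions within its own replicate. Colour gives the number of regions per bin, the dashed line marks equal ranks, and the regions lie along it (Spearman's rho 0.94).

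Annotated start sites held most of the mark. Of the 25183 replicated regions, 59.4% lay within 1 kb of the start of a protein-coding transcript, and they held 80.0% of the covered bases. A further 8.46% lay at the start of another kind of transcript, 5.14% in an exon, 11.98% in an intron and 14.9% between genes. Regions at protein-coding starts had a median width of 2046 bp and a median enrichment of 44.7, those in introns 524 bp and 3.79, and those between genes 625 bp and 5.39. In the replicates' own lists, which also hold the weak unshared peaks, the share at protein-coding starts was 52.4% in replicate 1 and 53.4% in replicate 2.

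Of 21829 protein-coding genes on chromosomes 1 to 19, X and Y, 14605 (66.9%) carried a replicated region within 1 kb of a start, here called a promoter peak. The replicates gave nearly the same genes: 14511 had a promoter peak in both lists, 157 only in replicate 1 and 125 only in replicate 2. The highest enrichment in the replicated list, 73.6, was at Dnajc11, a mitochondrial protein gene (chromosome 4, 151933376 to 151935419, build mm10). It was followed by the region between Rpn2, a subunit of the oligosaccharyltransferase, and Mroh8 (73.1), the region of Rnf114 and Spata2 (73.0) and Fem1b (73.0). The rest of the top 10 were Rpsa, a ribosomal protein gene, Atxn2l, Phrf1, Wdr18, Arf1, a small GTPase of the Golgi, and Hsp90aa1, a chaperone (72.0 to 72.9). This order is that of the pooled call and the replicates differed in it: of these 10 regions, that of Dnajc11 was the highest in replicate 2 (70.1, against 48.0 in replicate 1) and that of Fem1b in replicate 1 (62.6, against 68.1 in replicate 2). On the X chromosome 493 of 948 genes (52.0%) had a promoter peak. On the Y chromosome 4 of 183 did.

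CpG content at the most upstream start separated genes with and without a promoter peak. Of 8519 CpG-rich promoters (observed/expected CpG of at least 0.6 and GC of at least 55% over 1000 bp), 8453 (99.2%) had a peak. Of 4696 intermediate promoters, 89.7% had one, and of 8614 CpG-poor promoters (observed/expected CpG of at most 0.4), 1942 (22.5%) did. The class is that of the gene's most upstream start, while the peak could lie at any of its starts. A marked gene of the CpG-poor class can thus have its peak at a start of other CpG content. The odds ratio of rich against poor promoters was 440, and the two-sided Fisher's exact p lay below the smallest number the software can hold. Median domain width was 2553 bp for marked genes of the CpG-rich class and 1722 bp for those of the CpG-poor class, with the same limit. The tests of gene lists were not adjusted for CpG content.

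The facial gene lists were marked without exception. All 41 facial mesenchyme transcription factors carried a promoter peak, against 66.8% of other genes (adjusted p = 5.51e-07, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 28 lists). The members with the highest enrichment rank over both replicates were Satb2, a factor of palate and bone formation (enrichment 44.8 in replicate 1 and 48.7 in replicate 2), Snai2, a neural crest factor (42.9 and 50.1), Msx1, required for palate and teeth (41.7 and 47.4), and Twist1, a factor of head mesenchyme (43.4 and 45.0). All 35 facial signalling genes were also marked (adjusted p = 6.95e-06, Fisher's exact test), led by the receptor Fgfr1 (51.7 and 61.3), the ligand Pdgfa (48.3 and 54.9), the receptor Tgfbr2 (49.1 and 53.2) and Gli3, a transcription factor of hedgehog signalling (51.5 and 47.2). All 29 genes of the cleft-associated list, which shares members with both of these, had a promoter peak (adjusted p = 4.04e-05, Fisher's exact test), among them Kmt2d, an H3K4 methyltransferase (48.4 and 66.4). These tests take genes as units and describe the lists in these 2 replicates only. They were not adjusted for CpG content, and 99.2% of all CpG-rich promoters had a peak. Brain patterning, housekeeping and cell cycle genes were marked in full too, so full marking is not particular to the facial lists.

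The skeletal lists were marked to different extents. The osteoblast and bone matrix list had 9 of 15 members marked (adjusted p = 0.634, Fisher's exact test). Satb2, Runx2, the master regulator of osteoblasts (39.1 and 46.4), and Sparc, a bone matrix protein (41.7 and 41.6), had the highest enrichment ranks. Bglap, Dmp1, Ibsp and Mepe, all genes of bone or tooth mineralisation, were among the 6 without a promoter peak. In the cartilage list 17 of 18 members were marked (adjusted p = 0.0189, Fisher's exact test), with Sox9, the master regulator of cartilage (38.0 and 36.5), Col11a1 (33.3 and 34.2) and Sox6 (29.7 and 28.3) at the top. Col10a1, the collagen of hypertrophic cartilage, had none. With replicate 1's list alone 16 of 18 cartilage genes were marked and the call was lost (adjusted p = 0.0953, Fisher's exact test). The skeletal muscle list had 14 of 18 members marked (adjusted p = 0.509, Fisher's exact test). Mef2c (40.1 and 40.8) and Pax7 (14.0 and 19.8) led it, and Chrna1, Ckm, Myh8 and Tnnt3, genes of the differentiated fibre, had no peak in the replicated list. Chrna1 and Tnnt3 had one in replicate 1, Myh8 had one in replicate 2, and all 3 had one in the pooled list. There 17 of 18 members were marked and the muscle list passed (adjusted p = 0.0288, Fisher's exact test). Of the 14 marked in the replicated list, Acta1 (2.86 and 2.93) and Ttn (3.27 and 2.93) had the lowest ranks.

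All 19 epidermis and oral epithelium genes had a promoter peak (adjusted p = 0.00211, Fisher's exact test), with Klf5 (41.2 and 53.5), Epcam (30.1 and 37.4) and Perp (27.0 and 31.0) at the top. The tooth and hair placode list had 11 of 15 marked (adjusted p = 0.786, Fisher's exact test). Pitx2 (33.7 and 32.6) and the ectodysplasin gene Eda (26.4 and 32.7) led, and the unmarked members were the enamel matrix genes Ambn, Amelx, Amtn and Enam. None of the 57 keratin-associated protein genes, which serve the late hair shaft, had a peak in either replicate (adjusted p = 3.4e-27 for the replicated list, Fisher's exact test).

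Of the peripheral nerve and glia list 14 of 17 members had a peak (adjusted p = 0.264, Fisher's exact test), with Mpz (50.4 and 42.4), Six4 (30.1 and 47.5) and Erbb3 (32.3 and 41.5) highest. The region of Mpz, a myelin gene, also lies within 1 kb of a start of its neighbour Sdhc, so the mark there cannot be given to either gene. Fabp7, Phox2b and Plp1 had no peak. Of the olfactory and sensory placode neuron list 13 of 14 were marked (adjusted p = 0.0601, Fisher's exact test), Ebf1 (35.0 and 34.2) and Dlx5 (28.3 and 35.4) most strongly, and Omp, the marker of mature olfactory neurons, was the exception. Endothelial genes were marked in 13 of 14 cases (adjusted p = 0.0601, Fisher's exact test), with Kdr (24.6 and 42.0) and Sox18 (17.5 and 32.7) highest and Emcn without a replicated peak. Emcn had a peak in replicate 2 and in the pooled list, where all 14 were marked and the list passed (adjusted p = 0.0129, Fisher's exact test). Tie1, counted among the 13, had a peak in replicate 1 and none in replicate 2. Plvap (1.86 and 3.42) and Pecam1 (3.68 and 4.15) had the lowest ranks of the endothelial genes marked in both replicates. All 9 pericyte and smooth muscle genes had a peak (adjusted p = 0.0541, Fisher's exact test), led by Notch3 (44.0 and 48.3). With 1 start per gene the olfactory and the pericyte lists passed (adjusted p = 0.0389 and 0.0462, Fisher's exact test). In the melanocyte list 4 of 8 were marked (adjusted p = 0.509, Fisher's exact test). Mitf (47.1 and 51.5) was highest, the region of Pmel also lies within 1 kb of a start of Cdk2, and the pigment genes Dct, Mlana, Tyr and Tyrp1 had none.

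The lists of liver and pancreas products, of the eye, of blood and of the germ line had fewer marked members than the rest of the genome. This did not hold for the heart and foregut regulators. Of the liver and pancreas products 1 of 14 had a promoter peak, Apoa1 (adjusted p = 2.2e-05, Fisher's exact test), and Afp, Alb, Amy2a2 and Apoc3 were among those without. The macrophage and leukocyte list had 3 of 14 (adjusted p = 0.002, Fisher's exact test), with Cd14 (26.0 and 28.2) the strongest and Adgre1, Aif1, Cd3e and Cd79a unmarked. Its peaks at Cd68 and Spi1 were present in replicate 1 and absent from replicate 2. In the pooled list 42.9% of the macrophage genes had a peak and the call was lost (adjusted p = 0.102, Fisher's exact test). The erythroid list had 4 of 13 (adjusted p = 0.0226, Fisher's exact test), among them Klf1 (41.9 and 40.7), while Alas2, Gata1, Hba-a1 and Hba-x had none. The eye list had 5 of 16 (adjusted p = 0.0108, Fisher's exact test), with Atoh7 (33.0 and 33.7) far above Six6 (6.54 and 7.08) and Otx2 (4.83 and 8.26), and the lens and photoreceptor genes Crx, Cryaa, Cryba1 and Crybb1 without a peak. All regions of Six6 also lie within 1 kb of a start of its neighbour 4930447C04Rik. The pluripotency and germ line list had 5 of 15 (adjusted p = 0.0189, Fisher's exact test), with Esrrb (22.5 and 21.2) highest, and Ddx4, Dppa5a, Mael and Nanog unmarked. Heart and foregut organ regulators were marked about as often as other genes, 11 of 15 (adjusted p = 0.786, Fisher's exact test), with Foxa1 (21.3 and 24.9) and Gata6 (20.5 and 24.0) highest and Hnf1a, Hnf4a, Pdx1 and Sftpc unmarked. Of 1091 olfactory receptor genes 2 had a peak, Olfr1033 and Olfr94, and of 326 vomeronasal receptor genes 1 did, Vmn1r4, whose region also lies within 1 kb of a start of Nt5c3 (adjusted p = 1.77e-155 for the vomeronasal list, Fisher's exact test).

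Patterning genes of the brain and trunk carried the mark too. All 15 brain patterning genes had a promoter peak (adjusted p = 0.00881, Fisher's exact test), with Otx1 (25.4 and 28.6) and En1 (25.6 and 25.0) highest. Of the Hox genes, which give segments of the trunk and hindbrain their identity, 10 of the 12 of paralogue groups 1 to 4 were marked (adjusted p = 0.437, Fisher's exact test), led by Hoxa1 (29.0 and 32.0), and Hoxb1 and Hoxb3 were not. Of groups 5 to 13, 23 of 27 were marked (adjusted p = 0.0601, Fisher's exact test), and Hoxa6, Hoxb8, Hoxc11 and Hoxd12 were not. Hoxa7 (27.7 and 22.1) and Hoxd8 (20.7 and 20.2) were highest. Hoxc6 (2.34 and 2.35) and Hoxa9 (2.22 and 2.93) had the lowest ranks of those marked in both replicates. Hoxa11 had a peak in replicate 1 and none in replicate 2. The median of all peaks at protein-coding starts was 35.0 in replicate 1 and 39.3 in replicate 2. The Hox list of groups 5 to 13 passed the threshold with replicate 1's list alone (24 of 27, adjusted p = 0.024), with a window of 2.5 kb (adjusted p = 0.00838) and with the pooled list (adjusted p = 0.00916, all by Fisher's exact test). The housekeeping, cell cycle and ribosomal protein lists were marked almost throughout. All 19 of 19 housekeeping genes were (adjusted p = 0.00211, Fisher's exact test), led by Ubc (61.2 and 65.7, within 1 kb of a start of Gm10382 too). So were 15 of 15 cell cycle genes (adjusted p = 0.00881, Fisher's exact test), led by Rrm2 (51.7 and 59.1). Of the ribosomal protein genes 76 of 79 were marked (adjusted p = 2.17e-09, Fisher's exact test), and Rpl10l, Rpl39l and Rpl3l had no peak.

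**Figure D2:**
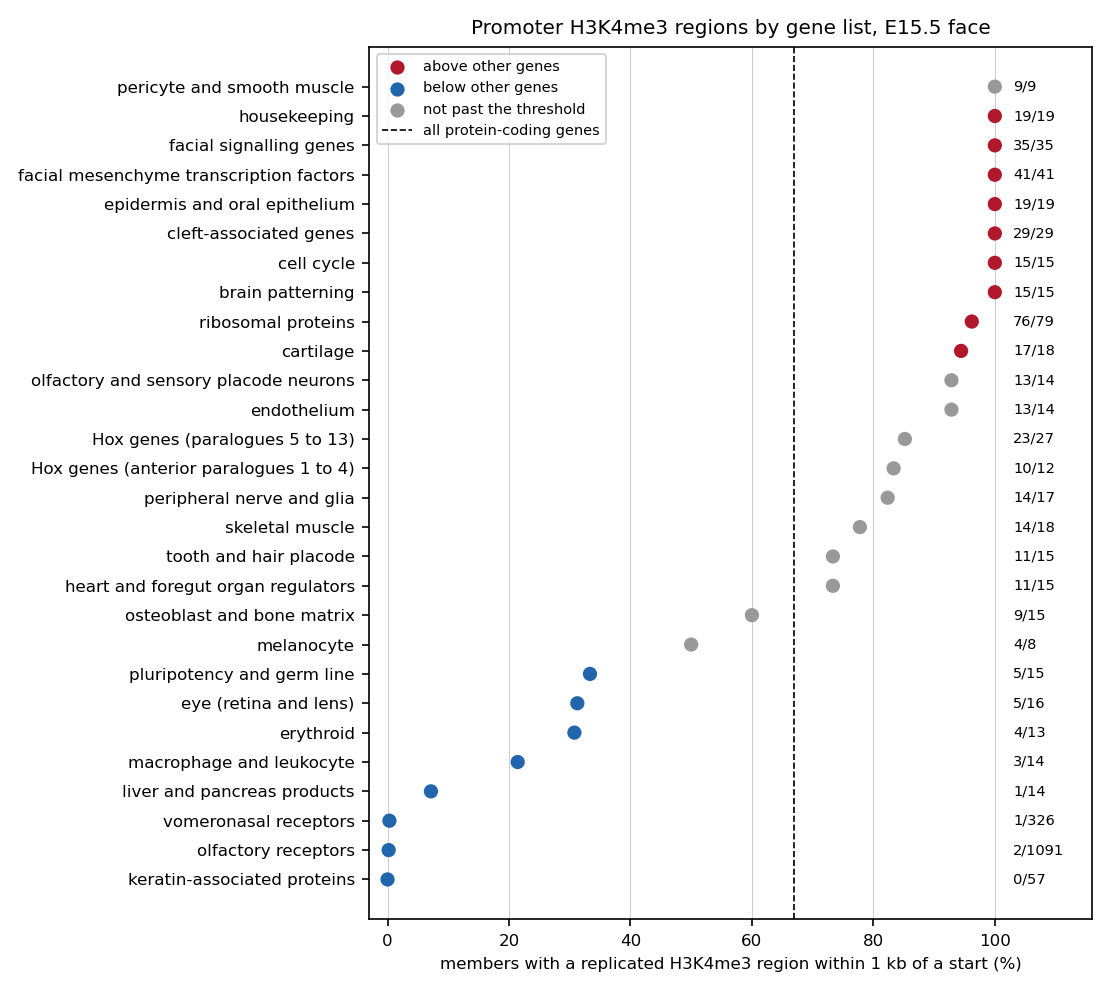
Share of the members of each gene list with a replicated H3K4me3 region within 1 kb of a start, in percent, with members marked and measured at the right; the dashed line is the share of all protein-coding genes (66.9%). Red and blue points passed the two-sided Fisher's exact test after Benjamini-Hochberg adjustment, above and below other genes; grey points did not.

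Of the fixed lists, the facial mesenchyme transcription factors had the widest marked domains. Regions within 1 kb of each other were merged, which gave 22280 domains with a median width of 1660 bp, of which 669 spanned at least 5000 bp and 52 at least 10000 bp. Domain widths in the replicates' own lists had a Spearman's rho of 0.94 across domains. The median width over all genes with a promoter domain was 2295 bp. The 41 facial mesenchyme transcription factors had a median of 8237 bp, more than in any of 10000 random lists of the same size (adjusted p = 0.0006, the smallest the permutations can give here), and the median was 7096 bp in replicate 1 and 7587 bp in replicate 2. Facial signalling genes had a median of 4510 bp and the cleft-associated list likewise 4510 bp, both with the same adjusted permutation p of 0.0006. The 9 marked osteoblast and bone matrix genes had 5127 bp (adjusted permutation p = 0.0006), with Satb2 at 12370 bp and Col1a1 at 9349 bp. Housekeeping genes (3741 bp) and epidermal genes (3682 bp) also were wider, with an adjusted permutation p of 0.0006. Klf5 had the widest epithelial domain, 6061 bp.

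Smaller differences in width were found for other lists. Ribosomal protein genes had a median of 2831.5 bp (adjusted permutation p = 0.00105) and cell cycle genes 3140 bp (adjusted permutation p = 0.0354). Cartilage genes had 3460 bp (adjusted permutation p = 0.00672), the olfactory placode list 3315 bp (0.0262), the tooth and hair placode list 3312 bp (0.0339) and brain patterning genes 3069 bp (0.0465). These last 4 calls depended on the regions merged or the replicate used: cartilage, tooth and brain lists lost them when only touching regions were merged (adjusted permutation p = 0.179, 0.427 and 0.544), the tooth and olfactory lists when regions within 3 kb were merged (0.1 and 0.0559), and the cartilage and brain lists with replicate 1's list alone (0.0867 and 0.13). Domains were narrower than in random lists at Hox genes of groups 5 to 13 (median 1060 bp, adjusted permutation p = 0.0006), the 5 marked pluripotency and germ line genes (909 bp, adjusted permutation p = 0.00672) and heart and foregut regulators (1505 bp, adjusted permutation p = 0.0262). The last of these reached 3406 bp when regions within 3 kb were merged (adjusted permutation p = 0.0801) and was lost with replicate 2's list alone (1791 bp, adjusted permutation p = 0.239). Lists that did not pass were skeletal muscle (1794.5 bp, adjusted permutation p = 0.0842), peripheral nerve and glia (2608.5 bp, 0.378), eye (1401 bp, 0.0664), endothelium (2382 bp, 0.791), pericyte and smooth muscle (2412 bp, 0.791) and Hox genes of groups 1 to 4 (1868 bp, 0.211). The muscle list passed as narrower with either replicate's list alone (1624 bp with adjusted permutation p = 0.0417 in replicate 1, and 803 bp with 0.0006 in replicate 2) and when only touching regions were merged (1555 bp, 0.0168). With only touching regions merged the eye list (1019 bp, 0.0168) and the Hox genes of groups 1 to 4 (1371 bp, 0.0115) passed as narrower as well. Random lists matched on CpG content and GC, chosen after the data were seen, were compared with the widths of the main setting only. None of these 3 lists passed there either (adjusted permutation p = 0.922 for muscle, 0.235 for eye and 0.452 for Hox genes of groups 1 to 4). Whether the narrow calls under the other settings hold against matched lists was not tested.

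**Figure D3:**
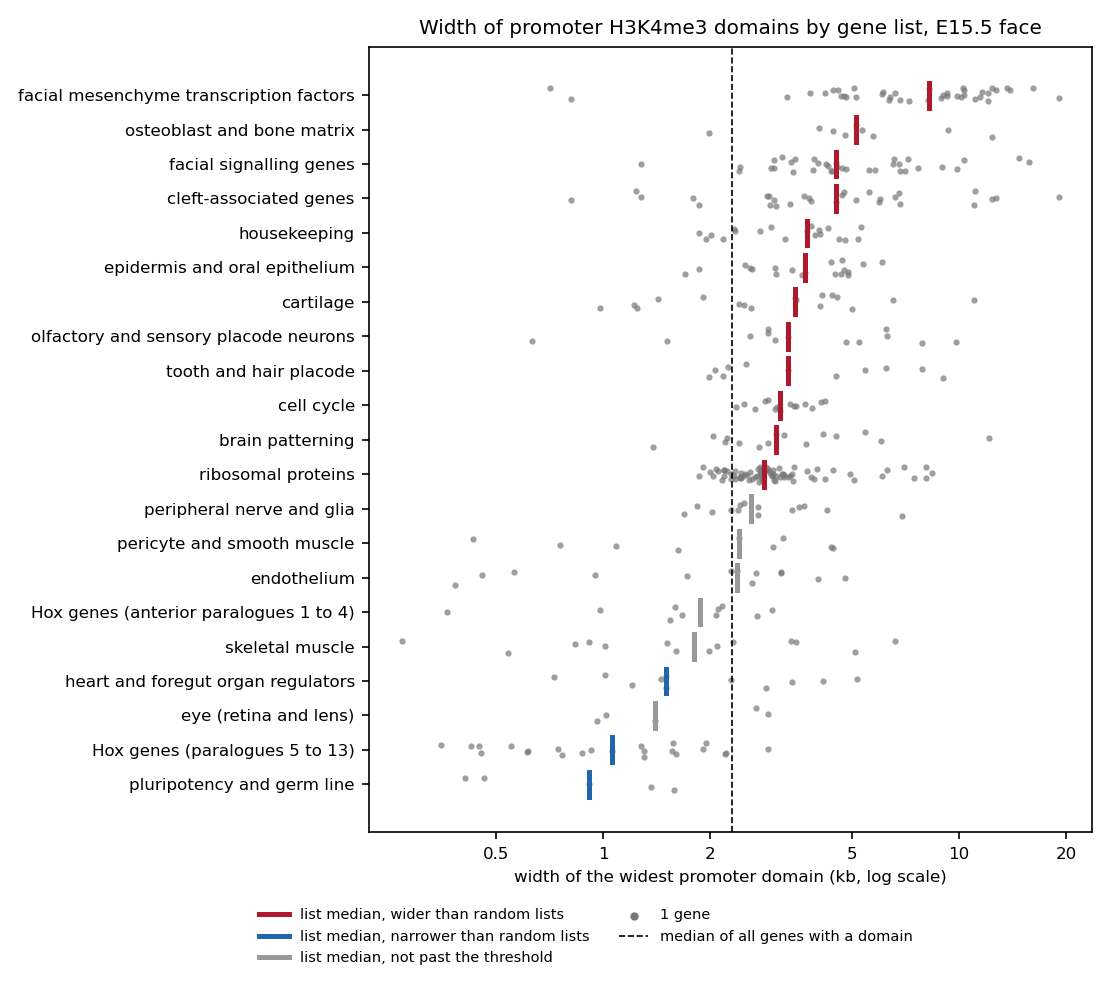
Width of the widest promoter domain of each marked gene (grey points, kb on a log scale) and the median of each list (bars), against the median of all genes with a domain (dashed, 2295 bp). Red bars are wider and blue bars narrower than random lists of the same size (permutation test, Benjamini-Hochberg adjusted), grey bars did not pass, and the facial mesenchyme transcription factors lie farthest to the right with a median of 8237 bp.

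In the replicated list, the widest domain spanned 19144 bp at Tfap2a, a transcription factor of the neural crest and face (chromosome 13, 40722396 to 40741539), and was 17131 bp wide in replicate 1, where Ebf3 was wider (17159 bp), and 17805 bp in replicate 2, where Tbx3 was wider (20803 bp). It merged 8 regions and reached from the body of the gene to beyond its most upstream start. Next were Trps1, mutated in a syndrome with a characteristic face (17421 bp, chromosome 15, 50874949 to 50892369), Ebf3 (17388 bp, chromosome 7, 137305997 to 137323384), Nfib (16992 bp, chromosome 4, 82497044 to 82514035) and Tbx3 (16352 bp, chromosome 5, 119667357 to 119683708). The Nfib domain measured 11388 bp in replicate 1 and 9670 bp in replicate 2, so its rank, like the first place of Tfap2a, rests on the pooled call. Meis2 (16180 bp), Tbx2 (15966 bp), the hedgehog receptor Ptch1 (15798 bp) and the ligand Wnt5a (14784 bp) followed. A domain of 14666 bp spanned the starts of several close genes (Kif22, Maz, Mvp, Pagr1a, Prrt2 and the predicted gene Gm42742). The remaining of the 20 widest domains, between 13172 and 14422 bp, were at Zfp503, at Setd1b with Rhof, and at Six2, Tnrc18, Irx5, Twist1, Mn1, Gata3 (with 4930412O13Rik and 9230102O04Rik), Kdm6b, an H3K27 demethylase, and 2010111I01Rik. Of these 20, 18 were also among the 20 widest in replicate 2's list and 16 in replicate 1's. The ranking depended on the merging distance: 6 of the 20 stayed when only touching regions were merged and 7 when regions within 3 kb were.

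Away from annotated starts the mark was weak and narrow. There were 4855 replicated regions more than 5 kb from any annotated start (19.3%), 1947 of them in genes and 2908 between genes. Their median width was 604 bp and their median enrichment 4.93, against 1930 bp and 40.9 for the 17097 regions at starts. In both replicates, 87.1% of them had a counterpart. Only 66 reached the median enrichment of regions at starts. The strongest lay 32307 bp from the nearest protein-coding start, that of Pum2 (chromosome 12, 8640182 to 8641827, enrichment 64.9), and was followed by regions nearest to Tln2 (chromosome 9, 67631859 to 67634782, 64.3), Fcgr4 (chromosome 1, 171037665 to 171039018, 62.9), Ppara (chromosome 15, 85669603 to 85674721, 62.2) and Trim27 (chromosome 13, 21199082 to 21201113, 55.02). None of these 5 lay inside a protein-coding gene of the GENCODE annotation. The region nearest to Tln2 lay within 1 kb of an mRNA start of Tln2 in the RefSeq annotation.

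Peaks without a counterpart in the other replicate were weak. Replicate 1 had 5776 of them and replicate 2 had 5268, of which 4894 and 4386 had no overlapping base there. Their median rank by enrichment was at percentile 15.1 of replicate 1's list and 13.1 of replicate 2's. Among them 16.7% in each replicate lay at protein-coding starts, and 40.0% and 40.9% in introns. The strongest peaks with no overlapping base in the other replicate reached an enrichment of 6.15 in replicate 1, inside Ethe1 (chromosome 7, 24601141 to 24601469), and 6.59 in replicate 2, at a start of the melatonin receptor gene Mtnr1a (chromosome 8, 45068934 to 45069341). The next 4 in replicate 1 lay inside Svop, Pbx1, Ggt1 and C77080 (5.93 to 6.14). The next 4 in replicate 2 lay inside Mcm3 and Vac14 and outside protein-coding genes, nearest to Gm11011 and Jph4 (5.71 to 6.10).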

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

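The replicated list held 10 regions on 6 unplaced scaffolds, outside the chromosomes used for the gene comparisons, and they are flagged as data those comparisons do not use, with enrichment between 4.16 and 43.2 (median 9.99). All 10 had a counterpart in replicate 1 and in replicate 2. No explanation was tested for them.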

How the results depend on the processing

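CpG-matched random lists, leaving out genes whose regions all cover another gene's window, and RefSeq starts were alternatives chosen after the data were seen. Genes with a promoter peak stayed between 14018 and 14821 under all 7 alternatives. The gap between CpG-rich and CpG-poor promoters stayed between 74.6 and 77.6 percentage points, but was not computed with 1 start per gene. Of 28 lists, 17 passed in share and 17 to 20 did under the alternatives, and of 21 lists 15 passed in width and 12 to 16 did. Over 224 comparisons of single lists in share, 2 calls were lost and 10 gained. Over 126 in width, 8 were lost with the direction kept, 7 were gained and 1 was lost with the direction reversed. No list reversed in share. The reversed one in width was that of heart and foregut regulators, which passed as narrower in the main analysis. With regions merged within 3 kb their median lay above that of random lists (3406 bp), but did not pass (adjusted permutation p = 0.0801). The cause was not tested. Sharing between replicates, 81.7% on average, was 84.6% with any overlap, 73.8% with 50% of both peaks, 85.1% at a q of 0.01 or less and 94.0% at 1e-05 or less. Replicated peaks found in both replicates, 93.6%, were 86.6% with 50% of both peaks, 89.5% at a q of 0.01 or less and 83.9% at 1e-05 or less, where fewer peaks remain to be matched. Spearman's rho between replicates, 0.94, was 0.92 at a q of 1e-05 or less and 0.97 with −log10 p. The share of regions at protein-coding starts, 59.4%, was 57.7% with a window of 500 bp, 65.6% with 2.5 kb, 49.8% in the pooled list, 62.6% at a q of 1e-05 or less, 51.8% with 1 start per gene, and 52.4% to 53.4% with 1 replicate left out. Of the 20 widest domains 6 stayed with only touching regions merged and 7 with 3 kb, and 16 to 18 with 1 replicate left out. Regions away from starts numbered 4855 beyond 5 kb, 8076 beyond 1 kb and 4329 without those near a RefSeq start. Peaks without a counterpart averaged 5522 per replicate and 1292 at a q of 1e-05 or less. The causes of these shifts were not tested beyond what each setting removes. Sharing, rank agreement and peaks without a counterpart need both replicates, so leaving 1 out gives no value. No paired analysis was possible because there is a single group. Depth is unknown and limits what weak peaks show.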

Other observations

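The gene families, the tRNA genes, the comparison of the X with autosomes, the CpG-matched widths of Hox genes and the tests of other regulators and of repeats were chosen after the data were seen. Gene families outside the fixed lists, some of whose members those lists hold, differed in the width of their domains. All 6 Iroquois factors were marked, with a median domain of 8257 bp (adjusted permutation p = 0.0005), and Irx5 reached 13874 bp. Irx5 is among the genes of the widest domains listed above, as are Nfib, Ebf3, Tbx3 and Tbx2. Their families were chosen after these widths were seen, so the permutation p of the Iroquois factors is not an independent test of width. All 12 LIM homeobox factors (4081.5 bp, adjusted permutation p = 0.00067), all 19 SOX factors (3460 bp, 0.0025) and 41 of 44 forkhead factors (3228 bp, 0.00067) were marked with domains wider than those of random lists, as were 39 of 44 collagen genes (3027 bp, 0.00086). Paired collagen genes, such as Col4a5 with Col4a6 (3027 bp) and Col4a1 with Col4a2 (6227 bp), had the same width and counted separately. The permutation test was not adjusted for this. The 4 NFI factors and 4 Ebf factors were all marked, too few for the width test. T-box factors divided: 15 of 17 were marked with a median of 2307 bp (adjusted permutation p = 0.965), while Tbx3, Tbx2, Tbx1 and Tbx15 had domains of 16352, 15966, 11050 and 10049 bp. Genes named Zfp were often marked (323 of 365, 88.5%, adjusted Fisher's exact p = 4e-21) with narrow domains (1908 bp, adjusted permutation p = 0.0005), and 28 of 54 clustered protocadherins had domains of 686 bp at the median (adjusted permutation p = 0.0005). Of 49 keratin genes 12 were marked (adjusted Fisher's exact p = 4.64e-09). On the Y chromosome the 4 marked genes were Ddx3y, Eif2s3y, Kdm5d and Uty. On the X, genes whose most upstream start had intermediate CpG content were marked less often than on autosomes (79.8% and 90.6%, adjusted Fisher's exact p = 2.49e-07). The difference did not pass for CpG-rich promoters (98.3% and 99.3%, adjusted Fisher's exact p = 0.147) or CpG-poor ones (93 of 487 and 23.2%, adjusted Fisher's exact p = 0.0526). The median enrichment percentile of marked CpG-rich promoters was 60.3 on the X and 81.0 on autosomes. The replicates pooled embryos of both sexes, and the number of X copies was not taken into account. These differences therefore need not be a property of X promoters.

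A second group of genes with the mark were tRNA genes, which the main annotation leaves out. Of 214 nuclear tRNA genes of the RefSeq annotation that lie more than 5 kb from any start of the main annotation, 126 (58.9%) had a replicated region within 1 kb, with a median enrichment of 33.6. Random positions on the same chromosomes, also more than 5 kb from any start of the main annotation, had one in 0.667% of cases. Beyond that limit they were not matched to the tRNA genes in distance from starts. None of the 43 cysteine tRNA genes among them was marked, while 14 of 17 leucine, 12 of 15 alanine and 6 of 6 phenylalanine tRNA genes were. A region near several tRNA genes counted for each of them. These shares and the median enrichment thus do not come from separate regions.

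The first pattern is the width of domains at facial mesenchyme transcription factors, 8237 bp at the median. Random lists matched on promoter CpG content and GC had medians whose central 95% ended at 2614 bp. Lists matched on the number and span of annotated protein-coding starts ended at 2682 bp. So neither property, as measured here, accounts for the width by itself. CpG content was taken over 1000 bp at the most upstream start and matched in coarse classes. How far CpG-rich sequence extends along the domains was not matched. Starts of other kinds of transcripts were not matched, and wide domains such as that of Tfap2a hold some. Whether those starts widen the domains was not tested. The 59 marked regulators of brain, heart, foregut and Hox lists were narrower by 6576 bp at the median (1661 bp, permutation p = 1e-05, the smallest the permutations can give). Of these 59, 33 were Hox genes, but brain patterning genes by themselves were narrower too (3069 bp, adjusted permutation p = 0.00364), although wider than random lists. So these regulators do not share the width of the facial list. Iroquois factors, a family chosen after the widths were seen, do reach that width, at 8257 bp. Wide domains are thus not limited to the facial list, but how common they are in other families cannot be read from a family chosen in this way. No biological explanation was tested.

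The second pattern is the set of 66 strong regions far from annotated starts. Starts missing from the main annotation are a likely source of many of them: 54.5% (36 regions) had a RefSeq start within 1 kb, against 10.2% of the 4789 weaker regions (Fisher's exact p = 1.44e-18). Of the 36, 19 were at tRNA genes and 13 at mRNA starts (1 at both), and regions near Fcgr4 and Trim27 were among the former and the region near Tln2 among the latter. The median share of soft-masked bases was 11.6%, with a 95% bootstrap interval that ended at 13.1%, against 9.93% in regions at starts. So repeats do not make up most of the bases of a typical region of the set. The share is taken over whole regions, so a short repeat inside a region cannot be excluded as its source. In the strongest region, near Pum2, 50.5% of the bases were soft-masked. The remaining 30, which include the regions near Pum2 and Ppara, stay open.

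The third pattern is the mark at Hox genes of groups 5 to 13, 85.2% of which had a promoter peak. Random lists matched on CpG content and GC had a median share of 92.6% (central 95% from 85.2% to 100%). The share lay at the lower edge of that range, with 1.61% of matched lists below it and 8.49% at or below it. These Hox genes were thus marked no more often than matched lists. Since the range ends at 100%, no share could lie above it, so the test cannot decide whether CpG content is enough. CpG content over 1000 bp at the most upstream start does not by itself account for their narrow domains. Matched lists had a median width of 2267 bp against 1060 bp (adjusted permutation p = 0.00047). The extent of CpG-rich sequence was not matched here either. Cells from another body region and repression of these genes were not tested.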
